A study of Drosophila melanogaster with 6 samples.

How the data were processed

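RNA from whole male w1118 flies, aged 30 days, was measured on Affymetrix Drosophila Genome 2.0 arrays. Per the labels' protocols, each of the 6 samples was a pool of 10 flies, total RNA was extracted with a phenol-based reagent, and 1.5 µg of it was turned into biotin-labelled cRNA in one cycle of amplification. Sample titles gave the diet (control or LCA at 50 µmol/l) and a replicate number, and each diet had 3 samples. The deposited value table held 18952 probe sets in 6 columns, 1 per sample. Its values are log2 signals as deposited by the authors: they run from 2.32 to 14.6, above what a natural log of a 16-bit scanner value allows (11.1) and within log2 (16). The method of summarizing probes, the background correction and the normalization were not given in the sources used here. The values of different arrays had nearly equal distributions, with sorted values within 0.10 of their mean over arrays, so the arrays had been brought to a common scale before deposit, and a change shared by most transcripts would not show. Because such summaries carry no detection call, no probe set could be said to be above background. No scanner files were analysed here, and no batch, slide or scan date was given in the sources used here.

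Probe sets were named through the platform annotation of GEO, updated through the gene table of Drosophila assembly Release 6 plus ISO1 MT, which was used for names alone. Of 18952 probe sets, 183 were array controls and were left out of the tests. Of the remaining 18769, 13647 had 1 gene symbol (13544 found in the gene table and 103 kept under the platform's symbol), 402 had several and 4720 had none here, and the last 2 kinds were tested but not named. A gene was represented by its probe set with the highest mean over all arrays, which gave 11982 genes. Of 12 named genes with several probe sets, 8 had all of them in the same direction, and 1 (Galphaq) had an opposite one at an unadjusted p under 0.05. Coordinates are not reported, since no sequence or build stands behind the value table. The smallest median absolute difference between any 2 arrays was 0.10, so no 2 arrays hold the same values.

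Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the deposited log2 values, LCA minus control, no covariate), with Benjamini-Hochberg adjustment over all probe sets, or over all genes for values of named genes, and a threshold of 0.05. The SE of a log2 difference is limma's moderated one. Gene lists (40, fixed in advance, 39 with at least 5 measured genes; the lysozymes fell below that) were tested with limma's camera with a preset correlation of 0.01 between genes, adjusted over the 39 lists. camera compares a list with all other genes. Each list was also adjusted over the list alone from limma's gene p-values. This adjustment does not control errors across the 39 lists, and "fell" or "rose" by it is a weaker call than one over all genes. Lists cover metabolism, detoxification, stress, immunity, nutrient signalling and lifespan, and markers of the other tissues of a whole fly. The tests, lists, alternatives and the rule for named genes were chosen before the data were examined. The rule named, in each direction, the 12 genes with the smallest p among those with non-overlapping groups and at least a 1.5-fold difference, since 0 genes passed the threshold that would have ranked them by size; up to 4 members with the smallest p of each list described; and 10 regulators, of which Thor and Hsp22 lacked a probe set of their own. Members of lists that were not called, and Cyp28c1 and PGRP-LF, are named where they passed over the list alone, a choice made after their values were seen. So was the naming of Dif, dl, Rel, Prosalpha4 and Prosalpha4T1, which did not pass.

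The fit was tested on simulated arrays with the real probe sets' means and limma's moderated spread, drawn independently, with 200 of 18769 probe sets changed: limma recovered 0% of 1.5-fold changes, 92% of 2-fold changes (with 18 false calls) and 98% of 3-fold changes (with 11 false calls). A simulated shift of −0.3 in the lipid synthesis and storage list was called by camera, with 0 of 37 other lists called. Genes were drawn independently there, so this run cannot show how often lists of correlated genes are called falsely. In the real arrays the estimated correlation within the lipid list was 0.248. RNA quality was read from 5 pairs of 3′ and 5′ control probe sets (2 of actin, 2 of GAPDH and 1 of eIF-4a). The first actin pair differed by 3.06 ± 0.04 in LCA and 2.50 ± 0.35 in control arrays (SD, n = 3 each; exact two-sided permutation p = 0.1, 0.333 after adjustment over the 5 pairs). Over the 183 control probe sets limma found 0 past its adjusted threshold (lowest adjusted p = 0.241) and 13 at an unadjusted p under 0.05.

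Alternatives were quantile normalization, median centring, leaving out probe sets with a mean below the median or the 25th percentile, a floor at each array's 25th percentile, eBayes with trend and robust options, array weights, the replicate number as a block, each sample left out in turn, thresholds with a 1.5-fold limit, camera with an estimated correlation, fry, the mean of a gene's probe sets, and leaving out probe sets whose names end in _s_at or _x_at. Chosen after seeing the data were an adjusted p of 0.10, the testis marker median of each array as a covariate, and the mean 3′ minus 5′ difference as a covariate. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.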

Results

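Transcript levels were measured on 6 Affymetrix arrays, each carrying labelled RNA from a pool of 10 whole male flies of the w1118 strain, a white-eyed laboratory stock that serves as wild type. The flies were 30 days old and had been fed control food or food with 50 µmol/l lithocholic acid (LCA). LCA is a secondary bile acid that gut bacteria of vertebrates make. Each diet had 3 arrays, and this number limits the precision. The labels do not say that the pools of a diet came from separate cultures, so p-values measure the spread between these pools, part of which may be technical. The median log2 signal of an array over 18769 probe sets lay between 6.31 and 6.35 in control arrays and between 6.38 and 6.39 in LCA arrays. Across probe sets, which are not independent replicates, Pearson correlations were 0.995 to 0.997 between LCA arrays, 0.984 to 0.994 between control arrays and 0.982 to 0.995 between diets. Control replicate 1 stood apart on the first principal component, which held 54.1% of the variance, at −42.7. The other control arrays lay at −15.4 and 11.97 and the LCA arrays at 7.43 to 21.4.

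The comparison of the diets asks which transcripts differ in flies fed LCA, in a study of this bile acid and fly lifespan. The smallest p-values belonged to immune peptides, a hormone and genes of unknown function, all lower in LCA flies. BomS2 and BomT2, short secreted peptides of the bomanin family that are induced through Toll signalling, differed by −0.91 ± 0.08 and −0.93 ± 0.08 on the log2 scale (LCA minus control, SE, 3 arrays per diet). BomS2 read 10.45 ± 0.06 in LCA flies and 11.36 ± 0.03 in control flies (SD, n = 3 each). Lst, the gene of limostatin, a peptide hormone that restrains insulin release, read 9.37 ± 0.03 in LCA flies and 10.32 ± 0.13 in control flies (SD, n = 3 each). Its difference was −0.95 ± 0.10 (SE). Among the 12 lower genes that the rule named were also pll, the kinase of the Toll pathway (−0.75 ± 0.09), and Idgf2, a secreted chitinase-like growth factor (−0.62 ± 0.08). So were Tmlh, an enzyme of carnitine synthesis (−0.95 ± 0.12), and Sfp24Bb, a seminal fluid protein (−1.01 ± 0.12). The others were CG18301 (−1.57 ± 0.20), CG32695 (−0.88 ± 0.11), CG10031 (−0.84 ± 0.09), CG13877 (−0.79 ± 0.08) and CG15203 (−0.79 ± 0.09).

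The 12 higher genes that the rule named included Cda9, a chitin deacetylase (0.92 ± 0.18), Cht8, a chitinase (0.67 ± 0.15), and sens, a zinc finger transcription factor of sensory organ development (0.62 ± 0.11). They also included feo, a microtubule-bundling protein of cell division (0.61 ± 0.15), and Rnf11, a RING finger protein (0.60 ± 0.11). The others had only annotation numbers: CG43123 (0.78 ± 0.12), CG17477 (0.75 ± 0.13), CG31077 (0.71 ± 0.15), CG15876 (0.65 ± 0.15), CG14841 (0.65 ± 0.16), CG3906 (0.62 ± 0.15) and CG3640 (0.60 ± 0.09). In each of these 24 genes the 3 LCA arrays lay on one side of the 3 control arrays, which the rule required. The signal of sens was low, with a mean of 5.26 in LCA flies and 4.63 in control flies, under the median of every array.

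None of these single genes passed the threshold. limma placed 0 of 18769 probe sets under an adjusted p of 0.05, and its lowest adjusted p was 0.0697. At an unadjusted p under 0.05, limma counted 3026 probe sets, 1413 higher and 1613 lower in LCA flies, where 938 would be expected if nothing differed. The groups did not overlap in 4229 probe sets (22.5%, where chance gives 10%), 1760 higher and 2469 lower. Under the second threshold, an adjusted p of 0.10 chosen after seeing the data, limma counted 54 probe sets, of which 52 were lower. At 2-fold or more with an unadjusted p under 0.05, 45 probe sets were lower and 1 was higher. At 1.5-fold or more the balance was the other way, with 268 lower and 352 higher. On simulated arrays with limma's moderated spread and independent noise, limma recovered 92% of 200 probe sets changed 2-fold and 0% of those changed 1.5-fold. Only 200 of 18769 probe sets were changed there, and a larger changed share was not simulated. Raising values under each array's 25th percentile to that level gave 6 probe sets past the adjusted threshold, all lower. Weighting the arrays gave 6861, in a fit that did not converge and set control replicate 2 at a weight of 24.0 against 0.22 to 1.26 for the other arrays.

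**Figure D1:**
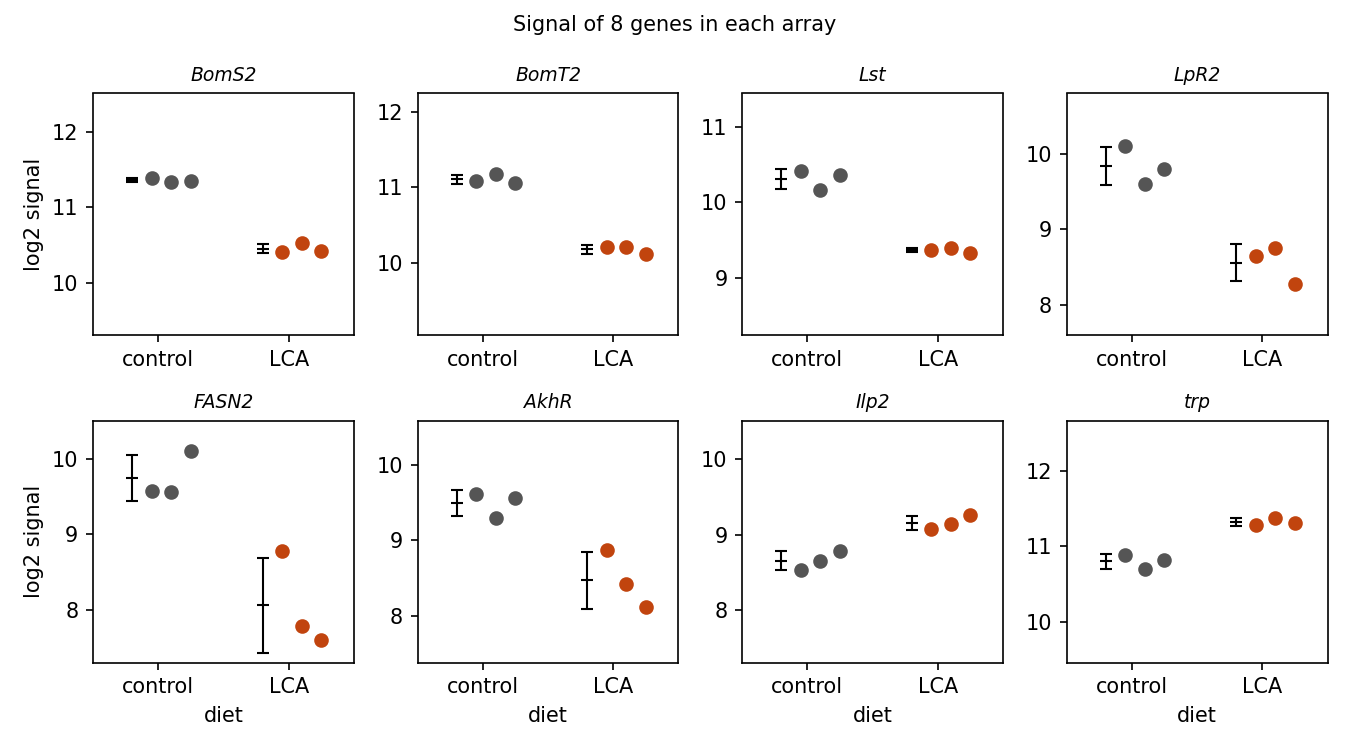
The vertical axes give the log2 signal of 8 genes and the horizontal axes the diet, with a point per array (3 per diet) and, to the left of the points, the mean with its SD. BomS2, BomT2, Lst, LpR2, FASN2 and AkhR lie lower in all 3 LCA arrays than in all 3 control arrays, and Ilp2 and trp lie higher; none of the 8 passed limma's adjusted threshold over all genes.

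Genes of fat synthesis, storage and use were lower in LCA flies as a group. Of 21 measured genes of lipid synthesis and storage, 20 were lower and 12 fell at an adjusted p under 0.05 when adjusted over the list alone, 0 over all genes. The median log2 difference was −0.37 (limma's camera, adjusted p = 5.51e-08; adjusted p = 0.469 with an estimated correlation). When adjusted over the list alone FASN2, a fatty acid synthase, fell (−1.69 ± 0.32, SE), as did Jabba, a lipid droplet protein (−0.88 ± 0.16). So did Lsd-1, a perilipin that coats lipid droplets (−0.87 ± 0.19), and mdy, a diacylglycerol acyltransferase (−0.62 ± 0.12). Of 19 genes of lipolysis and fatty acid oxidation, 16 were lower and 8 fell when adjusted over the list alone, with a median of −0.34 (camera adjusted p = 7.49e-06; adjusted p = 0.469 with an estimated correlation). Among them were AkhR, the receptor of the fat-mobilising adipokinetic hormone (−1.02 ± 0.20; its other probe set −0.65), Acadvl, an acyl-CoA dehydrogenase (−0.55 ± 0.10), and CPT2, a mitochondrial carnitine acyltransferase (−0.49 ± 0.10). All 11 lipoproteins and their receptors were lower and 3 fell when adjusted over the list alone. They were the lipophorin receptors LpR2 (−1.28 ± 0.17) and LpR1 (−0.56 ± 0.11; its other probe set −0.36) and Mtp, a lipid transfer protein (−0.42 ± 0.11). That list had a median of −0.27 (camera adjusted p = 9.09e-05; adjusted p = 0.469 with an estimated correlation). LCA replicate 3 weighed on the second of these lists, whose median was −0.22 without it, and array weights moved the median of the third to −0.18. In the first list the median per array, relative to each gene's mean, was −0.08, −0.12 and −0.37 in LCA replicates 1 to 3. It was 0.20, 0.13 and 0.27 in control replicates.

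Genes of sugar metabolism were lower in the same arrays. Of 23 measured genes of glycolysis, trehalose and glycogen, 20 were lower and 11 fell when adjusted over the list alone, 0 over all genes, with a median of −0.29 (camera adjusted p = 3.77e-06; adjusted p = 0.511 with an estimated correlation). Those that fell included AGBE, the glycogen branching enzyme (−0.76 ± 0.15), and fbp, the fructose bisphosphatase of gluconeogenesis (−0.63 ± 0.15). Others were Pepck2, a phosphoenolpyruvate carboxykinase (−0.53 ± 0.13), and Tret1-1, a trehalose transporter (−0.41 ± 0.10). LCA replicate 3 lay furthest down. The list median per array, relative to each gene's mean, was −0.04, −0.04 and −0.35 in LCA replicates 1 to 3. It was 0.18, 0.13 and 0.19 in control replicates. Markers of other tissues moved with the fat and sugar genes, and with the lower lists named further on. Testis markers had a median of 0.57 and photoreceptor markers of 0.36, both higher in LCA flies, and fat body markers of −0.27. The log2 difference between 3′ and 5′ probe sets of the array controls, a measure of how intact the labelled RNA was, averaged 3.503 ± 0.09 in LCA flies and 3.24 ± 0.24 in control flies (SD, n = 3 each; exact two-sided permutation p = 0.1, the smallest that 3 against 3 arrays allow).

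**Figure D2:**
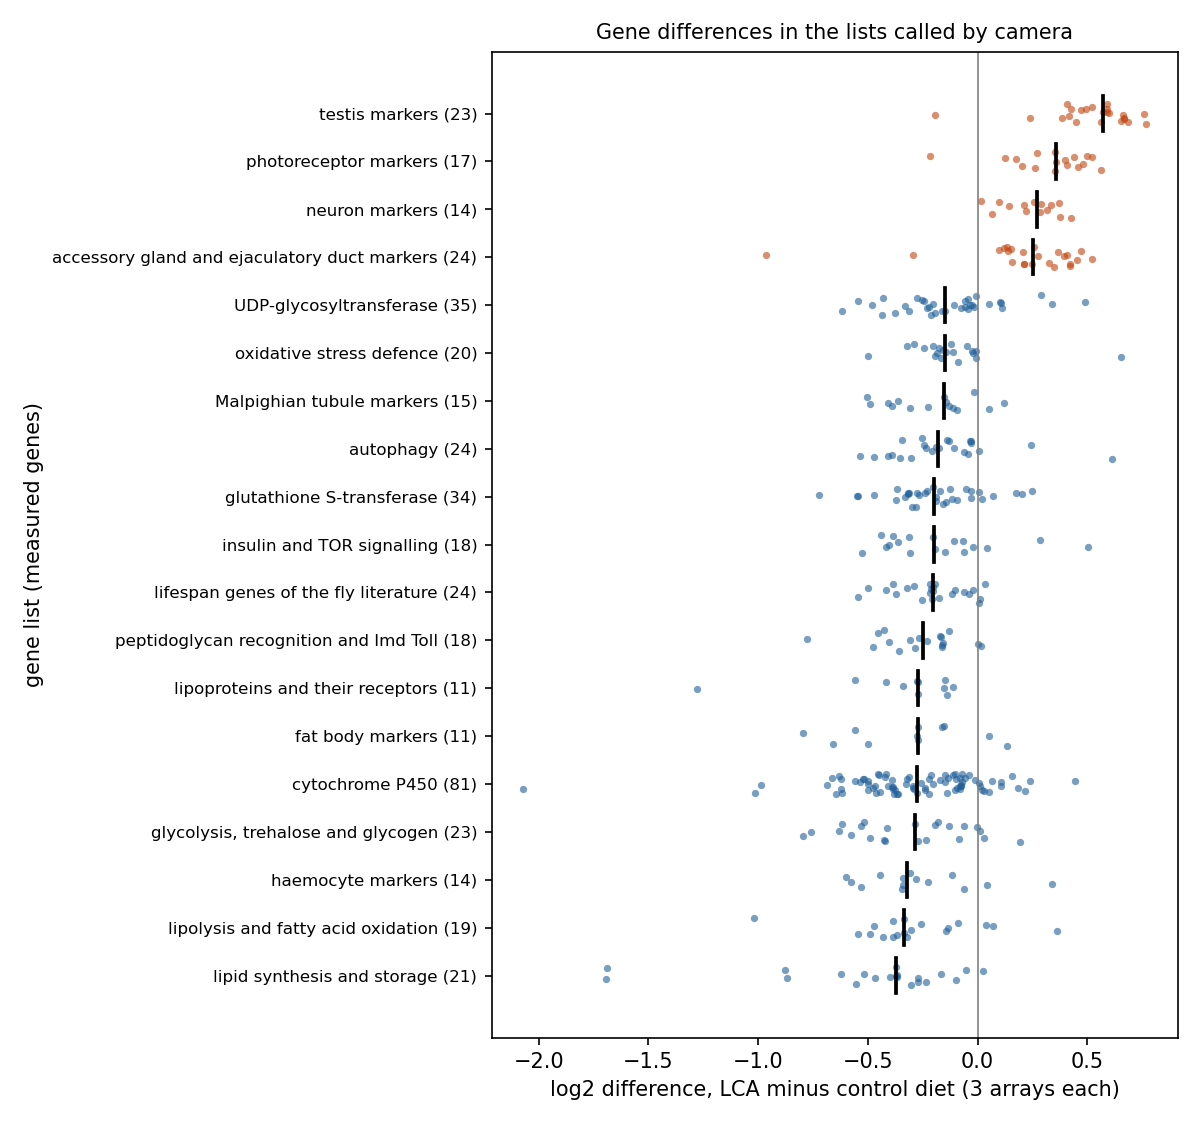
Each point is the log2 difference (LCA minus control diet, horizontal axis) of 1 gene in one of the 19 lists that camera called with its preset correlation, and each vertical bar is the median of the list named on the vertical axis, with its number of measured genes. Medians run from −0.37 for lipid synthesis and storage to 0.57 for testis markers; 0 of the 19 lists passed with an estimated correlation.

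Detoxification genes were lower as groups. Of 81 cytochrome P450 genes, 68 were lower, and when adjusted over the list alone 14 fell and 1 rose, with 0 past the threshold over all genes. Their median was −0.28 (camera adjusted p = 6.78e-09; adjusted p = 0.469 with an estimated correlation). By the test over the list alone, Cyp6a9 (−0.62 ± 0.09), Cyp6a19 (−0.53 ± 0.10) and Cyp6a20 (−0.48 ± 0.09), of a family that includes detoxifying enzymes, fell, as did Cyp301a1 (−0.52 ± 0.09). Cyp301a1 and Cyp6a19 were dim, with mean log2 signals of 4.35 and 4.07 in LCA flies and 4.87 and 4.60 in control flies, under the median of every array. Cyp28c1 rose by 0.45 ± 0.12. Of 34 glutathione S-transferases, which conjugate reactive compounds, 28 were lower and 0 passed over the list alone. The median was −0.20 (camera adjusted p = 0.00215; adjusted p = 0.537 with an estimated correlation), and GstE9 had a difference of −0.72 ± 0.15, while its other probe set was at −0.03. Of 35 UDP-glycosyltransferases, which attach sugars to small molecules, 28 were lower and 0 passed over the list alone, with a median of −0.15 (camera adjusted p = 0.0232; adjusted p = 0.537 with an estimated correlation) and Ugt301D1 at −0.62 ± 0.15. Both transferase calls were lost without control replicate 2 (medians −0.10 and −0.07, camera adjusted p = 0.0784 for both). The second was also lost without LCA replicate 3 (−0.10, camera adjusted p = 0.165) and among probe sets above the median signal (−0.22, camera adjusted p = 0.0502). Control replicate 3 left out gave −0.31 for the glutathione S-transferases, as did array weights, and control replicate 1 left out gave −0.07 for the UDP-glycosyltransferases. The testis markers and the 3′ to 5′ difference of each array were added to the fit after seeing the data. With the testis markers in the fit the P450 median was −0.17, and with either of the 2 both transferase lists lost the call (camera adjusted p from 0.180 to 0.517). Both measures were higher in every LCA array than in every control array. A call lost with either, here or in the lists below, therefore does not separate that measure from diet.

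Genes of microbe recognition and of Imd and Toll signalling, tested as 1 list, were lower, while antimicrobial peptides went both ways. Of 18 genes of peptidoglycan recognition and Imd and Toll signalling, 16 were lower and 5 fell when adjusted over the list alone, 0 over all genes. The median was −0.25 (camera adjusted p = 6.78e-05; adjusted p = 0.469 with an estimated correlation), and −0.17 with the testis markers in the fit. Those that fell included GNBP3, a receptor for fungal glucans (−0.78 ± 0.18), and nec, a serpin that restrains Toll activation (−0.48 ± 0.10). They also included Tl, the Toll receptor (−0.45 ± 0.12), cact, the inhibitor of the Toll transcription factors (−0.43 ± 0.11), and PGRP-LF, a peptidoglycan recognition protein of the Imd pathway (−0.40 ± 0.11). Of the transcription factors of both pathways, Dif (−0.16 ± 0.08), dl (0.02 ± 0.13) and Rel (−0.29 ± 0.16) did not pass. A further probe set of Tl differed by 0.07 and one of cact by −0.18. Of 14 antimicrobial peptides, 8 were lower and 6 higher (median −0.08, camera adjusted p = 0.0691, adjusted p = 0.537 with an estimated correlation). When adjusted over the list alone, BomS2, BomBc3 (−0.91 ± 0.14), BomS4 (−0.90 ± 0.15) and the antifungal peptide Drs (−0.74 ± 0.17) fell, and Drsl5, a peptide related to Drs, rose by 0.45 ± 0.13. Haemocyte markers, genes of blood cells, were lower in 12 of 14 and 2 fell when adjusted over the list alone. They were PPO1, a prophenoloxidase of melanisation (−0.60 ± 0.08), and Nplp2, a secreted peptide precursor (−0.44 ± 0.08). Their median was −0.32 (camera adjusted p = 0.00167; adjusted p = 0.469 with an estimated correlation). It was −0.19 without control replicate 2 and −0.17 with the 3′ to 5′ difference in the fit. With the testis markers in the fit it was −0.07 and the call was lost (camera adjusted p = 0.146).

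Nutrient signalling, lifespan, autophagy and antioxidant lists were lower in LCA flies. Of 18 genes of insulin and TOR signalling, 15 were lower, and when adjusted over the list alone 6 fell and 1 rose, 0 over all genes (median −0.20, camera adjusted p = 0.0060; adjusted p = 0.537 with an estimated correlation). Ilp2, an insulin-like peptide of brain neurosecretory cells, rose by 0.50 ± 0.10 by the test over the list alone. By the same test ImpL2, a secreted protein that binds insulin-like peptides (−0.53 ± 0.11), REPTOR, a transcription factor held back by TOR (−0.44 ± 0.12), and foxo, a transcription factor held back by insulin signalling (−0.42 ± 0.09), fell. Of 24 lifespan genes taken from the fly literature, 21 were lower and 6 fell when adjusted over the list alone, among them Indy, a citrate transporter (−0.55 ± 0.10), and magu (−0.37 ± 0.09). That list had a median of −0.21 (camera adjusted p = 9.04e-05; adjusted p = 0.511 with an estimated correlation) and shares 11 of its genes with other lists. Of 24 autophagy genes, 21 were lower and 0 passed over the list alone (median −0.18, camera adjusted p = 0.000799; adjusted p = 0.511 with an estimated correlation), with Atg13, of the kinase complex that starts autophagy, at −0.47 ± 0.11. Of 20 genes of oxidative stress defence, 19 were lower and 0 passed over the list alone (median −0.15, camera adjusted p = 0.0101; adjusted p = 0.537 with an estimated correlation), with Cat, the catalase, at −0.50 ± 0.14 and Gclc, of glutathione synthesis, at −0.29 ± 0.08.

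Control replicate 1 weighed on these 4 lists. Without it the medians were −0.08 for insulin and TOR signalling, −0.09 for the lifespan genes, −0.12 for autophagy and −0.10 for oxidative stress defence. All 4 were still called by camera with the preset correlation. The lifespan median was −0.32 without control replicate 3. The insulin and TOR call was lost without probe sets that may match several transcripts (median −0.13, camera adjusted p = 0.0964), and the oxidative stress call after quantile normalization (−0.15, camera adjusted p = 0.0612) and without LCA replicate 3 (−0.09, camera adjusted p = 0.0604). With the testis markers of each array in the fit, all 4 calls were lost. Since these markers were higher in every LCA array than in every control array, this does not separate testis RNA from diet. Camera gave adjusted p = 0.334 for insulin and TOR signalling (median −0.02), 0.221 for the lifespan genes (−0.04), 0.0801 for autophagy (−0.09) and 0.119 for oxidative stress defence (−0.07). With the 3′ to 5′ difference in the fit, the insulin and TOR median was −0.31 and the oxidative stress call was lost (−0.07, camera adjusted p = 0.213).

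The regulators named in advance stayed close to their control level or were somewhat lower, and 0 of them passed limma's adjusted threshold over all genes. Hr96, a nuclear receptor of xenobiotic and sterol responses, differed by 0.03 ± 0.20 (negative under quantile normalization or median centring), Sod2, the mitochondrial superoxide dismutase, by −0.02 ± 0.09 (positive or negative depending on the scaling) and mTor, the TOR kinase, by −0.06 ± 0.10. Sirt1, a protein deacetylase, differed by −0.21 ± 0.13, AMPKalpha, the catalytic subunit of the energy-sensing kinase, by −0.23 ± 0.08, Sesn, a sestrin, by −0.31 ± 0.10, and EcR, the ecdysone receptor, by −0.34 ± 0.10. EcR was dim, with a mean of 4.72 in LCA flies and 5.06 in control flies. Thor and Hsp22 had no probe set of their own.

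Markers of the testis, accessory gland, eye and nervous system were higher in LCA flies. Of 17 photoreceptor markers, 16 were higher and 13 rose when adjusted over the list alone, 0 over all genes (median 0.36, camera adjusted p = 1.26e-08; adjusted p = 0.469 with an estimated correlation). Among them were trp, a channel of phototransduction (0.52 ± 0.09), inaD, the scaffold of the phototransduction complex (0.56 ± 0.10), and Arr1, an arrestin (0.41 ± 0.08). Galphaq, a G protein subunit, rose too (0.40 ± 0.08), while another of its probe sets was lower, at −0.36 with an unadjusted p under 0.05. All 14 neuron markers were higher and 1 rose when adjusted over the list alone, nSyb, a synaptic vesicle protein, by 0.38 ± 0.08. The list's median was 0.27 (camera adjusted p = 0.000254; adjusted p = 0.537 with an estimated correlation). Of 24 accessory gland and ejaculatory duct markers, 22 were higher, and when adjusted over the list alone 7 rose and 1 fell (median 0.25, camera adjusted p = 2.51e-05; adjusted p = 0.537 with an estimated correlation). Acp32CD and Acp36DE, seminal proteins, rose by 0.52 ± 0.09 and 0.41 ± 0.09, and Ebp, a protein of the ejaculatory bulb, fell (−0.96 ± 0.15). Of 23 testis markers, 22 were higher and 0 passed over the list alone (median 0.57, camera adjusted p = 1.97e-06; adjusted p = 0.537 with an estimated correlation), with fzo, a mitofusin of spermatids, at 0.47 ± 0.15. The testis median per array, relative to each gene's mean, was −0.84, −0.20 and 0.14 in control replicates 1 to 3 and 0.21, 0.28 and 0.37 in LCA replicates. Without control replicate 1 the list median was 0.29 (camera adjusted p = 5.72e-05).

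With the testis markers in the fit, the medians of the neuron and accessory gland markers were both 0.45. With the 3′ to 5′ difference in the fit, the neuron call was lost (0.09, camera adjusted p = 0.179) and the accessory gland median was 0.14.

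Fat body and Malpighian tubule markers were lower. Of 11 fat body markers, genes of the organ that stores fat and secretes haemolymph proteins, 9 were lower and 0 passed over the list alone (median −0.27, camera adjusted p = 0.0232; adjusted p = 0.469 with an estimated correlation), and 7 of them also stand in other lists. Hex-C, a hexokinase, differed by −0.80 ± 0.26 and Tsf1, a transferrin, by −0.56 ± 0.23, with its 3 probe sets from −0.87 to −0.27. Of 15 Malpighian tubule markers, genes of the excretory organ, 13 were lower and 0 passed over the list alone (median −0.15, camera adjusted p = 0.0234; adjusted p = 0.625 with an estimated correlation), with the organic anion transporter Oatp58Db at −0.49 ± 0.17. The fat body call was lost without control replicate 3 (median −0.23, camera adjusted p = 0.0683), without LCA replicate 3 (−0.20, camera adjusted p = 0.0505) and after quantile normalization (−0.23, camera adjusted p = 0.0541). Its median was −0.18 without control replicate 1. The Malpighian call was lost without control replicate 2 (−0.13, camera adjusted p = 0.115), without LCA replicate 3 (−0.12, camera adjusted p = 0.166) and among probe sets above the median signal (−0.15, camera adjusted p = 0.0517). The Malpighian median was −0.31 without control replicate 3, −0.30 without LCA replicate 2 and −0.28 with array weights. Both calls were lost with the testis markers in the fit (camera adjusted p = 0.119 and 0.693) or with the 3′ to 5′ difference (0.169 and 0.581).

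**Figure D3:**
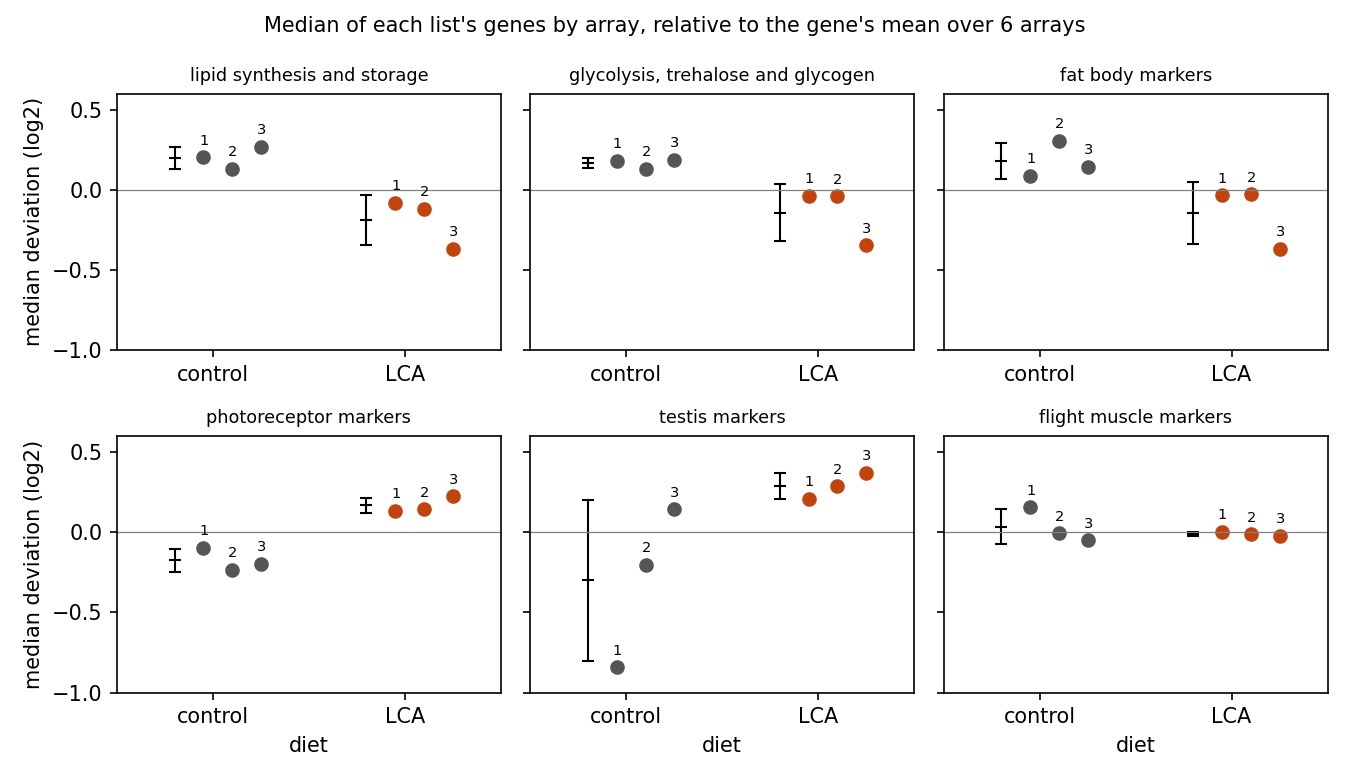
Each point is the median over a list's genes of the log2 deviation from the gene's mean over the 6 arrays (vertical axis), by diet (horizontal axis), with the replicate number beside it and the mean of the 3 arrays with its SD to the left. The testis markers of control replicate 1 lie at −0.84, while the photoreceptor markers lie between 0.13 and 0.22 in LCA flies and between −0.23 and −0.10 in control flies.

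The other 20 lists were not called. The closest to the threshold was sterol transport, ecdysteroid synthesis and nuclear receptors (19 of 30 lower, median −0.09, camera adjusted p = 0.0582). In it Npc2g (−0.63 ± 0.14) and Npc2h (−0.58 ± 0.13), of a family that binds sterols, and Hnf4, a nuclear receptor of lipid use (−0.37 ± 0.08), fell when adjusted over the list alone. By the same test Mal-B2, a maltase of the carbohydrate digestion list, fell (−0.96 ± 0.13), as did Stat92E, the transcription factor of JAK-STAT signalling (−0.46 ± 0.11), and cry, the blue-light receptor of the clock (−0.41 ± 0.10). Among odorant-binding proteins Obp56g (−0.64 ± 0.12) and Obp18a (−0.46 ± 0.10) fell and Obp49a rose by 0.44 ± 0.09, and beyond the antimicrobial peptides the other uncalled lists had 0 past it. Medians were −0.08 for the citric acid cycle (camera adjusted p = 0.0945), −0.11 for carbohydrate digestion (0.135), −0.06 for mitochondrial ribosomal proteins (0.163), −0.08 for oxidative phosphorylation (0.164), −0.05 for cuticle proteins (0.179), −0.04 for flight muscle markers (0.213), −0.13 for the JNK pathway and stress targets (0.237) and −0.10 for sirtuins and AMPK (0.281). They were 0.06 for the circadian clock (0.477), −0.02 for Turandot and JAK-STAT genes (0.562), −0.03 for cytosolic ribosomal proteins (0.618), −0.01 for odorant-binding proteins (0.692) and −0.05 for female markers (0.914). At camera adjusted p = 0.998, heat shock genes had a median of −0.02, the ER unfolded protein response of −0.02, the proteasome of −0.01, and the trypsins and Jonah proteases and the midgut markers of 0.03 each. The median, the mean or the direction of the test differed in sign in 8 of these lists (heat shock, ER unfolded protein response, trypsins and Jonah proteases, oxidative phosphorylation, cytosolic ribosomal proteins, proteasome, female and midgut markers). A median near 0 does not mean that a list's members stayed level. The proteasome list, matched by name, also took in relatives of its subunits, and 19 members were higher and 21 lower. Prosalpha4 was at −0.42 ± 0.08 and its relative Prosalpha4T1 at 0.62 ± 0.18. Members higher and lower were 22 and 51 for oxidative phosphorylation and 12 and 29 for cytosolic ribosomal proteins. The medians of the trypsins, midgut markers, cytosolic ribosomal proteins and proteasome changed sign, or came to 0, under quantile normalization or median centring. Of all 39 lists tested, camera with its preset correlation called 19, 15 lower and 4 higher. With an estimated correlation 0 passed (lowest adjusted p = 0.469), and 0 passed the directional test of limma's fry, which does not compare a list with other genes (lowest adjusted p = 0.0785). Its mixed test, which takes members moving either way, called 22. Other splits of the 6 arrays into 3 and 3, which mix the diets, gave 6 to 18 lists called by camera with its preset correlation.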

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

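The tests with an adjusted p of 0.10, the testis markers or the 3′ to 5′ difference were chosen after seeing the data. The count of probe sets past limma's adjusted threshold was 0 with all arrays and stayed 0 (0 to 0) with each sample left out, after quantile normalization or median centring, with either filter on dim probe sets, with trend and robust options and with both covariates. It was 6 with a floor at the 25th percentile (all lower), 6861 with array weights (3602 higher, 3259 lower), 620 at an unadjusted p under 0.05 with at least 1.5-fold (352 higher, 268 lower) and 54 at an adjusted p under 0.10. The array-weight fit did not converge, and the causes of these differences were not tested. camera called 19 lists with all arrays, 16 to 22 with each sample left out, 14 with either covariate, of which 9 (testis markers) and 13 (3′ to 5′ difference) were among the 19, and 17 to 22 with the other settings that keep its preset correlation. It called 0 with an estimated correlation and fry called 0 with its directional test and 22 with its mixed test, which takes members moving either way; the estimated correlations reach 0.792 between neuron markers, against the preset 0.01. With the testis markers in the fit the median of the trypsins and Jonah proteases was 0.337 and that of the midgut markers 0.19, both called as higher, where camera's direction without them was lower (medians 0.032 each), and that of the testis markers themselves was −0.011, which the covariate's construction fixes. Over 105 named genes, 1570 of 1670 values kept their direction and side of the threshold or changed sign without being called in either setting (13), and 100 passed, all with array weights. Whether the replicate numbers pair the samples is not known. Correlations of same-numbered deviations were 0.26, −0.02 and 0.02, which are too few to settle it. The replicate block gave 0 probe sets past the adjusted threshold and 19 lists, the same counts as without it. At an unadjusted p under 0.05 limma counted 3535 probe sets with the block and 3026 without it. A pseudocount was not tried, since the values are already logarithms.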

Other observations

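Apart from the fixed gene lists and the main limma and camera results repeated here, all tests and groups in this part were chosen after the results were seen. The older antimicrobial peptides were regrouped by name after a first look. A further group, of hydrocarbon genes, was dropped because its members had been picked from the lower genes. Members of 3 gene families were mostly lower in LCA flies. All 8 measured bomanins were lower, with log2 differences from −0.93 (BomT2) to −0.56 (BomT3), a median of −0.82 and groups apart in all 8. The imaginal disc growth factors, secreted chitinase-like proteins, were lower in 6 of 6, with Idgf1 and Idgf5 both at −0.78 and a median of −0.52. Of 19 neprilysin-like proteins, a family of secreted or membrane metallopeptidase relatives, 17 were lower and 2 higher (median −0.19; groups apart in 10), with Nepl9 at −1.15 ± 0.16 and Nepl6 at −0.83 ± 0.13; Nepl3, at 0.04, changed sign with the scaling. Adjusted over these 4 families, camera with an estimated correlation gave p = 0.0576 for the bomanins and the neprilysin-like proteins and 0.0837 for the growth factors. The fourth family, 6 older antimicrobial peptides, had a median of −0.01 (camera adjusted p = 0.764 with an estimated correlation) and varied between pools of the same diet: AttD read 10.27 in LCA replicate 1 against 5.64 and 5.53 in the other LCA arrays, and DptB read 11.56 there and 10.19 in control replicate 1, against 7.29 to 8.23 elsewhere.

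A pair of single genes picked because their differences were large had a wide spread within LCA flies. Cyp4g1, the P450 that makes hydrocarbons, read 12.97, 13.31 and 13.90 in control arrays and 12.62, 11.20 and 10.14 in LCA arrays (difference −2.07 ± 0.60). FASN3, a fatty acid synthase, read 9.57, 9.52 and 10.41 against 9.43, 8.02 and 6.97 (−1.69 ± 0.60). limma's adjusted p over all genes was 0.196 for Cyp4g1 and 0.244 for FASN3.

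Lower fat and sugar genes could reflect a smaller share of fat body RNA in LCA flies. Such a loss alone would raise the markers of all other tissues alike, and they moved apart. The 31 photoreceptor and neuron markers averaged 0.29 ± 0.17 (SD over genes) and the 44 muscle, midgut and Malpighian tubule markers −0.10 ± 0.23. The difference was 0.396, with a 95% interval over arrays of 0.03 to 0.76. A permutation over genes, which are not independent, gave p = 1e-05, the smallest that 100000 permutations give. The tissues were grouped into these sides after their list shifts had been seen, so their moving apart is not an independent test of fat body loss. The interval does not allow for that choice. The mean shift of the lipid list, with the testis markers or the 3′ to 5′ difference in the fit, went from −0.50 ± 0.13 (SE) to −0.489 ± 0.205 and −0.485 ± 0.195, and that of the sugar list from −0.32 ± 0.09 to −0.34 ± 0.14 and −0.28 ± 0.13. camera with its preset correlation kept both lists either way, while the 95% intervals, a stricter rule set after those calls were seen, all include 0, with larger SEs than before (to 0.165 and 0.136 for the lipid list). Dilution by testis RNA alone would lower the markers of every other tissue, and the photoreceptor and neuron markers were higher by a mean of 0.292 ± 0.080 (SE over arrays, 95% interval 0.07 to 0.51). These markers had been called as higher before the comparison was chosen, so it is not an independent test of dilution. The covariate fit and the lipid shift relative to muscle, midgut and Malpighian tubule markers, −0.40 ± 0.16 (−0.83 to 0.04), were tried before it and did not decide. Dilution or a smaller share of fat body RNA, as a part of the shifts, stays open. So do RNA quality, since its interval includes 0, and a response to LCA, which was not tested.

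Higher testis markers may come from 1 control pool low in testis RNA. Without control replicate 1 the mean shift of the list went from 0.52 ± 0.28 to 0.271 ± 0.147 (SE), and both intervals include 0, so this explanation and a difference between the diets cannot be told apart with 2 or 3 control pools.

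Lower bomanins could also follow from less fat body RNA, since the fat body makes them. The bomanins shifted by −0.77 ± 0.08 (mean, SE) and the fat body markers by −0.32 ± 0.11, and relative to those markers the bomanins were lower by a mean shift of −0.454 ± 0.062 (95% interval −0.63 to −0.28), which a smaller share of fat body alone would not give if the bomanins depend on that tissue no more than the markers do. The bomanins were made a family after their low values had been seen, and the interval does not allow for that choice. With the testis markers in the fit the bomanin shift was −0.81 ± 0.13. A response to LCA stays open and was not tested.

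With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The diets gave 0 probe sets past limma's adjusted threshold and so did the other splits (highest 0; all 10 as large). At an unadjusted p under 0.05 the diets gave 3026 probe sets, more than the highest other split with 2135, in which LCA replicate 1 joined control replicates 1 and 2 (1 of 10 splits as large). For the lists that camera called with its preset correlation, the diets gave 19 and the other splits, each of which mixes the diets, 6 to 18 (1 of 10 as large). Calls with the preset correlation thus also arise in number when the arrays are grouped otherwise than by diet.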
